A study of Mus musculus with 4 samples.

How the data were processed

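Hearts of mice were profiled by droplet single-cell RNA sequencing in 4 libraries, 1 for each of 4 groups: a control, a sham, cecal ligation and puncture (CLP, a mouse model of sepsis), and CLP with low-level tragus stimulation, called CLP plus stimulation here. The libraries were made with the Chromium 3' v3 kit, per the labels' protocols. The deposited matrices hold raw UMI counts per gene and cell barcode, which the authors made with Cell Ranger 5.0.0 per the file headers. Alignment with STAR to mm10 is named in the submitters' processing notes. Each matrix lists 32285 genes, and the smallest barcode total was 500 UMIs in every library. The number of animals behind a library and the time of sampling are not given in the sources used here. Gene coordinates were taken from the GENCODE vM21 annotation of GRCm38, in which all 409 of the 409 named or listed genes had an entry.

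Barcodes with at least 500 UMIs and 200 genes, and at most 20% of their UMIs from mitochondrial genes, were kept. In control, sham, CLP and CLP plus stimulation, 31, 83, 63 and 32 barcodes had fewer genes and 335, 487, 347 and 154 had a higher mitochondrial share. Doublets were scored within each library with Scrublet as implemented in scanpy 1.11.5. The barcodes with the highest scores, 0.8% per 1000 barcodes of the library, were left out, which came to 2039 (12.8%), 728 (7.63%), 611 (6.99%) and 624 (7.07%) barcodes. Of 43074 barcodes, 37616 cells were kept, with 13568, 8285, 7741 and 8022 in the 4 groups. Their median depth was 2996, 5341, 5491 and 5010.5 UMIs, so the control library was the shallowest per cell.

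Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen across libraries, and 30 principal components were computed with no integration of libraries. Cells were joined to their 20 nearest neighbours, edges were weighted by shared neighbours, and clusters were found with leidenalg 0.10.2 at resolution 1. The 33 clusters were named from markers fixed before the data were examined. A cluster took the class whose markers were on average at least 1 log2 unit above the median cluster after adding 5 CPM, with at least 3 markers detected in at least 10% of its cells. It also had to score at least 1 log2 unit above the next class and to hold no more markers of another class than of its own among its 10 genes of highest fold. This scoring rule and its thresholds, unlike the markers, were settled after the data had been seen. It named 29 clusters, in 14 classes, and left 4 unnamed. Clusters of T cells, NK cells and innate lymphoid cells were merged. All classes are called by their markers, as in macrophage-like.

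Each library gives a single value per class, so no test was made and no p-value is given. Shares of kept cells carry exact (Clopper-Pearson) 95% intervals. UMI counts were summed over the cells of a class in each library, and levels are counts scaled by the total UMIs of the class (CPM) with exact Poisson intervals. Log2 ratios used a prior count of 0.5. Ratios of single genes and of shares carry exact conditional binomial intervals. A gene list was summarised by the median log2 ratio of its members with at least 20 counts over the compared libraries, with an interval from 2000 Poisson draws of the counts. The percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these libraries only. All intervals cover counting error only, not the spread between animals. A gene at 0 in a library was set against a floor of 3 counts over the class in that library.

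The design fixed 21 gene lists, which were examined in 39 combinations of list and class. Aldoa, Clec7a, Cxcl11, Mx1 and Mx2 had no count row of their own and were left out. The rule for single genes was also fixed beforehand. It named the 3 genes with the highest and the 3 with the lowest log2 ratio in the macrophage-like, neutrophil-like, endothelial-like and fibroblast-like classes, among genes with at least 50 CPM and 20 counts in the higher library. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and sex-linked genes, unnamed gene models, markers of another class and genes over 10 times as high in another class were passed over. It further named every measured member of the M1 and M2 lists, and the 2 highest and 2 lowest members of the other lists. Not every gene these rules named is printed. The extremes are printed for the lists the report describes, and other lists are given by their medians with examples. The macrophage comparison of CLP plus stimulation with sham was not part of the fixed design.

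The calculation was tested on simulated data with 200 genes changed by known folds, in 8 combinations of class and comparison over 5955 to 13503 genes. The counting intervals held the true ratio for 95% to 97.0% of the changed genes. A simulated list with a true median of 1 was estimated at 0.99 to 1.04. Cluster naming returned 7 of 7 simulated classes. These were drawn from the summed sham counts of classes that the same rule had already named, so little else could result. The outcome checks the calculation only and says nothing on mixed or low-UMI clusters.

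Alternatives fixed before the data were examined were mitochondrial limits of 10% and none, at least 1000 UMIs and 500 genes, doublets kept, and Leiden resolutions of 0.5 and 2. For shares, immune cells as the total and a joint macrophage and monocyte class were tried. For lists, TMM scaling with edgeR 4.0.16, 5 CPM added to both values, no count minimum, and cells thinned to 770, 740 or 1257 UMIs (macrophage-like, endothelial-like and fibroblast-like) were tried. After the data had been seen, further alternatives left unnamed cells out of the total, counted cluster 10 as neutrophil-like or cluster 25 as macrophage-like, left out proliferating cluster 29, or left out M2 members that are also cell type markers. Thinning left out 395, 143, 44 and 50 shallower macrophage-like cells, 343, 118, 214 and 113 endothelial-like cells, and 330, 49, 42 and 59 fibroblast-like cells in the 4 groups. TMM moved log2 ratios of CLP over sham by 0.24 in macrophage-like, 0.14 in endothelial-like, 0.09 in fibroblast-like and 0.30 in neutrophil-like cells. For CLP plus stimulation over CLP the shifts were 0.03, 0.08, 0.20 and -0.29. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3.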

Results

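The heart cells of 4 mouse groups were sequenced, with 1 library per group: control, sham, CLP and CLP plus stimulation. Tragus stimulation is an electrical stimulation at the outer ear, where a branch of the vagus nerve ends. The series title poses the question of whether such stimulation eases the failing heart of sepsis through macrophages of the M2 state. In textbook terms M1 macrophages are inflammatory and M2 macrophages are tied to resolution and repair. The libraries held 59465046, 58028279, 58330756 and 54611436 UMIs over 15964, 9538, 8741 and 8831 barcodes. Median UMIs per barcode were 2993.5, 5141.5, 5113 and 4560, and median genes were 1281, 1789, 1752 and 1563. With 1 library per group, no difference has a replicate check. Values in parentheses are 95% intervals that cover counting error only.

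Macrophage-like, endothelial-like and fibroblast-like cells were the most common named classes in the control, sham and CLP libraries. In CLP plus stimulation, unnamed cells (18.7%) and monocyte-like cells (9.17%) outnumbered endothelial-like cells (8.34%). Different clusters held most of a class in different libraries. Cluster 0 held the largest part of the macrophage-like cells in control (45.4%) and sham (49.6%), cluster 9 held 92.0% in CLP and cluster 4 held 92.6% in CLP plus stimulation. Cluster 9 was led by Cxcl13, Saa3 and Ccl12, and cluster 4 by Rgs1, Saa3, Nlrp3 and Il1rn, all genes of immune activation or stress. Among endothelial-like cells the largest clusters were 1 in control (56.5%) and sham (67.6%), 8 in CLP (75.4%) and 16 in CLP plus stimulation (97.2%). Among fibroblast-like cells they were 2 in control (59.4%) and sham (61.0%), and 3 in CLP (82.4%) and CLP plus stimulation (87.4%), which was led by Prg4, Serpina3n and Dcn. Neutrophil-like cells came mostly from cluster 26 in control (97.2%) and sham (98.6%) and from cluster 17 in CLP (96.5%) and CLP plus stimulation (100%). A cluster mostly from 1 library may be that library and not a separate type.

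The unnamed cells made up 3.21%, 2.63%, 4.10% and 18.7% of kept cells in control, sham, CLP and CLP plus stimulation. Cluster 10 accounted for 0.00737%, 0.0362%, 1.34% and 16.9%, had a median of 984.5 UMIs, and scored alike for fibroblast and neutrophil markers. Cluster 19, between pericyte and endothelial markers, held 1.91%, 1.62%, 2.16% and 0.0374%. Cluster 25, between macrophage and monocyte markers and led by MHC class II genes, Retnla and Ccl17, held 0.884%, 0.978%, 0.594% and 1.81%. Cluster 32, between smooth muscle and fibroblast markers, held 0.405% in control and no cells elsewhere.

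**Figure D1:**
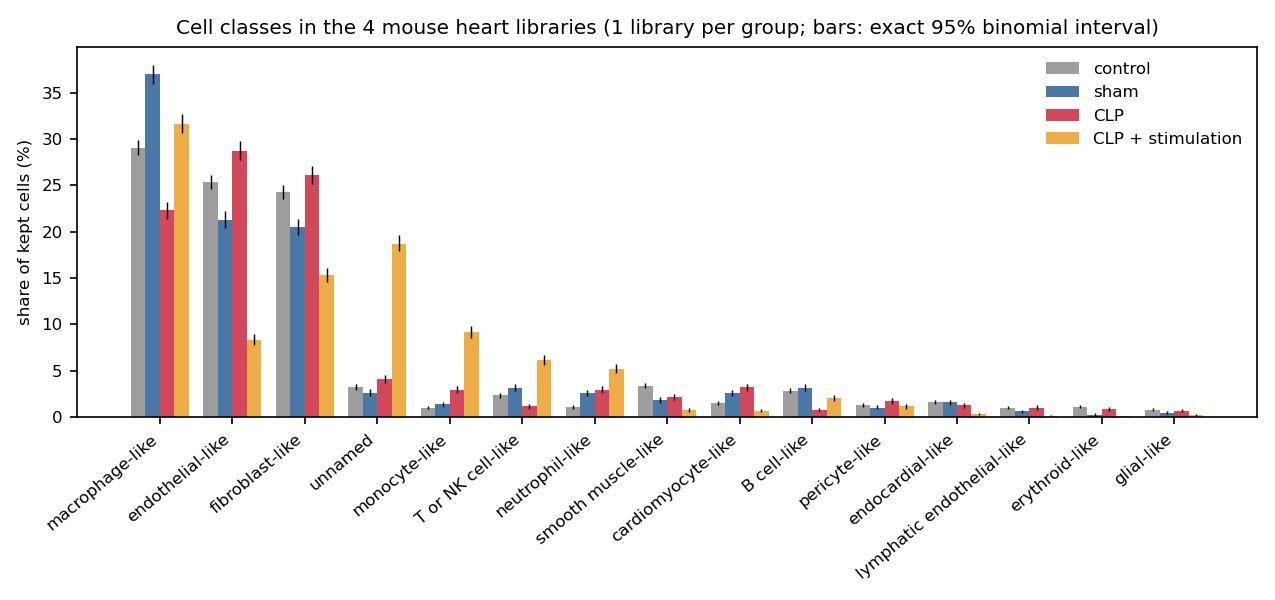
Share of kept cells (percent, vertical axis) of each cell class in the 4 libraries, with bars for the single library of each group and lines for exact 95% binomial intervals. Macrophage-like cells stood at 37.0% in sham, 22.3% in CLP and 31.7% in CLP plus stimulation, where unnamed cells reached 18.7%.

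Sham over control gives the background, which holds both the sham procedure and any difference between libraries. Macrophage-like cells were 29.1% (28.3 to 29.8) of control cells and 37.0% (35.9 to 38.0) of sham cells. Within them, genes of the interferon response and of the M1 state were higher in sham. The median log2 ratio of the M1 list was 0.46 (0.26 to 0.59), with 15 of 19 measured members higher, including the chemokines Ccl5 at 3.85 and Cxcl10 at 1.88. The M2 list lay at -0.06 (-0.12 to -0.03), with 8 of 20 members higher. Interferon response medians were 0.58 in macrophage-like, 0.22 in endothelial-like and 0.27 in fibroblast-like cells. The acute phase list in fibroblast-like cells lay at 0.19 (0.16 to 0.29), and a difference in the endothelial activation list, at -0.03 (-0.14 to 0.10), was not detectable at this depth. Endothelial-like cells of sham were also higher in cell cycle genes, at 0.87 with 18 of 20 higher, and lower in immediate early genes, at -0.43 with 14 of 16 lower, and glucocorticoid response genes, at -0.31.

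CLP over sham asks what sepsis did to the heart's cells. Macrophage-like cells were a smaller share of cells in CLP, at 22.3% (21.4 to 23.2), than in sham, at 37.0% (35.9 to 38.0), a log2 ratio of -0.73 (-0.82 to -0.64). Monocyte-like cells were more common, at 2.97% (2.60 to 3.37) against 1.36% (1.13 to 1.64), while B cell-like cells were fewer, at 0.788% (0.603 to 1.01) against 3.13% (2.76 to 3.52). The monocyte-like class was cluster 12 alone, which scored 3.88 for monocyte and 2.84 for neutrophil markers. Its neutrophil markers were 26877.5 CPM in CLP and 1894 CPM in sham, so the class may not hold monocytes only. Endothelial-like cells stood at 28.7% (27.7 to 29.7) against 21.3% (20.4 to 22.2), and fibroblast-like cells at 26.1% (25.2 to 27.1) against 20.5% (19.6 to 21.3). Neutrophil-like cells were 2.96% (2.59 to 3.36) of CLP and 2.60% (2.26 to 2.96) of sham cells, and the log2 ratio of 0.19 (-0.09 to 0.46) was not detectable at this depth. Kept cells had similar median depths, 5491 UMIs in CLP and 5341 in sham. As a share of immune cells alone, macrophage-like cells were 73.9% of CLP and 78.3% of sham, a log2 ratio of -0.08, and neutrophil-like cells were 9.81% and 5.49%, a log2 ratio of 0.84.

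In macrophage-like cells of CLP, most M2 genes were lower than in sham, and the M1 list was split. Saa3, an acute phase serum amyloid gene (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700 in GRCm38), reached 57551 CPM in CLP against 0.285 CPM, or 5 counts, in sham. Its log2 ratio was 17.48 (16.40 to 19.24). The B cell chemoattractant Cxcl13 was 7.32 and haptoglobin, Hp, 7.29 log2 units higher. Gpr34, a lipid-sensing receptor, at -6.98, the lectin Mgl2 at -6.39 and the MHC class II chain H2-Eb1 at -5.49 were the lowest of the eligible genes with at least 50 CPM in sham. Neutrophil markers moved with the class, from 189.9 CPM in sham to 3807 CPM in CLP, of which Lcn2, also an acute phase gene, made up 3170 CPM. Saa3 was also found in B cell-like cells of CLP, at 27001 CPM.

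The M2 list had a median of -0.82 (-1.19 to -0.75), with 14 of 19 measured members lower and a percentile of 0.02 among matched random lists. The mannose receptor Mrc1 (ENSMUSG00000026712, chromosome 2, 14229392 to 14332057) was 239.7 CPM (231 to 248) in CLP and 806 CPM (793 to 819) in sham, a log2 ratio of -1.75. Mgl2, Ccl24 (-4.71), Retnla (-3.67), Clec10a (-3.23) and Folr2 (-1.99) were further below. Stab1 at -1.495, Egr2 at -1.45, Irf4 at -1.30, Tgfb1 at -0.82, Pparg at -0.78, Il10 at -0.60, Klf4 at -0.44 and the haemoglobin scavenger receptor Cd163 at -0.36 completed the lower members. Arginase 1, Arg1, went the other way, with 175 counts in CLP and 0 in sham, at least 82.5-fold higher, as did Chil3 at 3.04, Tgm2 at 1.87, the interleukin 4 receptor Il4ra at 1.42 and Myc at 0.19.

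The M1 list had a median of -0.51 (-0.65 to -0.37) and a percentile of 2.11, with 12 of 19 members lower, but a mean of 0.18. The scavenger receptor Marco at 5.75, the formyl peptide receptor Fpr2 at 4.79 and Cd38 at 1.88 were higher, with Ptgs2 at 0.99, Socs3 at 0.63 and Il1a at 0.44. Interleukin 1 beta, Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139), was 311 CPM (301 to 321) against 144 CPM (139 to 150), a log2 ratio of 1.11. Chemokines and interferon-linked members were lower: Ccl5 at -2.38, Irf1 at -1.94, Cxcl9 at -1.77 and Cxcl10 at -1.69. Cd40 at -0.77, Cd86 at -0.73, Il6 at -0.72, Tnf at -0.69 and Irf5 at -0.51 were also lower. Il23a at -0.23 and Cd80 at -0.13 lay within counting error and turned positive under TMM scaling. The median of all genes in the class was -0.24, so the M1 list stood 0.27 log2 units below it and the M2 list 0.58 below. With cells thinned to 770 UMIs the M1 median was -0.12, and with TMM scaling -0.27.

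Genes of antigen presentation and of tissue residency showed the lowest list medians of the class. All 9 MHC class II genes measured were lower, with a median of -4.22 (-5.44 to -4.13), from the class II transactivator Ciita at -6.54 and H2-Eb1 at -5.49 to H2-Oa at -4.06 and the protease Ctss at -0.46. Markers of other antigen-presenting cells were lower too, dendritic markers at 5.49 CPM against 27.4 CPM in sham and B cell markers at 9.28 CPM against 28.8 CPM. The resident cardiac macrophage list lay at -1.70 (-1.79 to -1.66), with 15 of 16 members lower. Ccl24 and the growth factor Igf1 (-4.08) were lowest, and F13a1 at 0.11 and Mertk at -0.11 highest, Mertk turning positive under TMM scaling. The monocyte-derived list lay at 0.86 (0.57 to 1.33), with 14 of 17 members higher, from Arg1 and Hp down to S100a4 at -0.42 and the chemokine receptor Ccr2 at -3.17. Monocyte markers in the class summed to 983 CPM in sham and 1073 CPM in CLP. Phagocytosis and efferocytosis genes lay at -0.76 (-0.89 to -0.69), with 16 of 18 lower; Timd4 at -3.71 and Gas6 at -3.48 were lowest, and Msr1 at 1.83 and Marco highest. Inflammatory cytokine and chemokine genes lay at 0.28 (0.12 to 0.32), with the granulocyte factor Csf3 at 6.60 and the receptor antagonist Il1rn at 3.57 highest and Ccl8 at -3.11 and Il6 lowest. Interferon response genes lay at -0.32 (-0.48 to -0.27), close to the median of all genes in the class, with Usp18 at 1.65 and Zbp1 at 1.48 highest and Gbp3 at -2.09 and Ifit2 at -1.90 lowest.

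**Figure D2:**
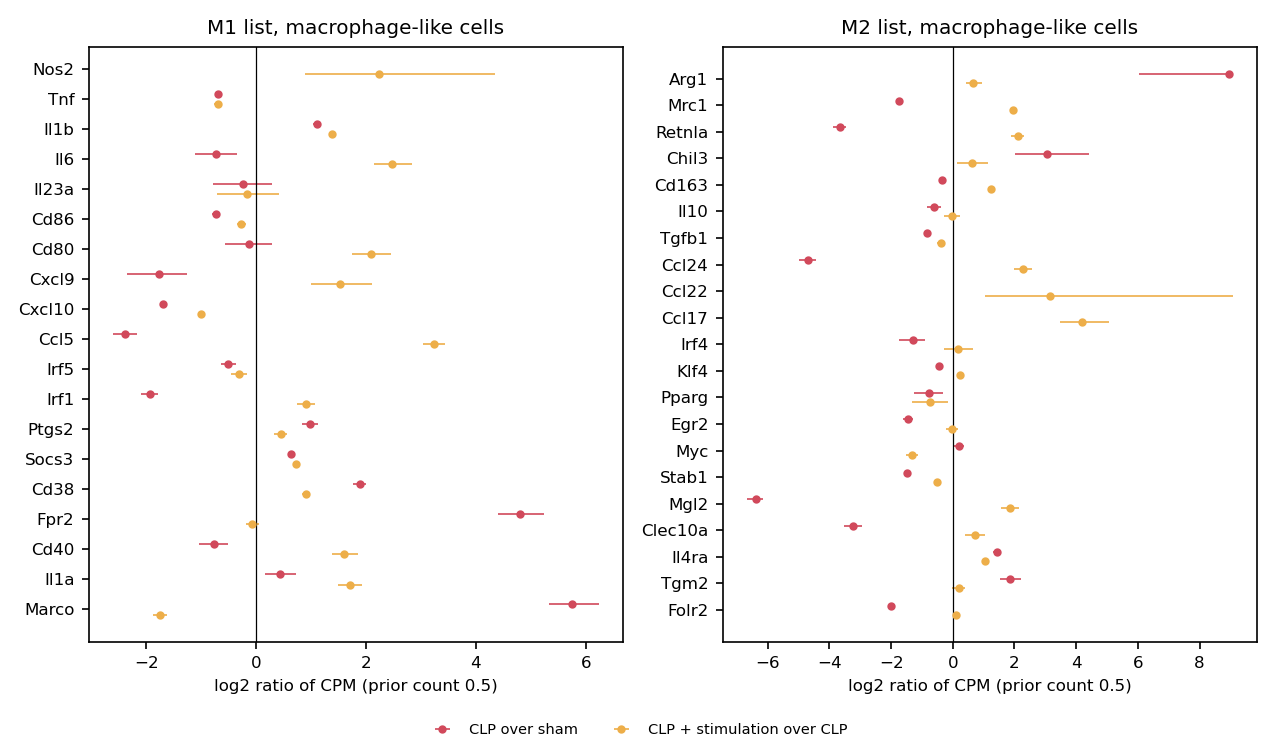
Log2 ratio of CPM (horizontal axis, prior count 0.5) of measured M1 and M2 members in macrophage-like cells, for CLP over sham and CLP plus stimulation over CLP, with lines for 95% counting intervals; not every M1 member is drawn, and Arg1 had 0 counts in sham, so its ratio has no upper bound. In CLP over sham, 14 of 19 M2 members lay below 0, and in CLP plus stimulation over CLP 15 of 21 M2 members and 12 M1 members lay above it, with Il10 crossing 0 under TMM scaling.

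Endothelial-like cells of CLP carried more transcripts of activation, interferon response and glucocorticoid response. The endothelial activation list had a median of 1.53 (1.36 to 1.63), with 18 of 22 members higher and a percentile of 100. The glycoprotein gene Lrg1 (119 CPM against 6.17 CPM, log2 ratio 4.26) and the leukocyte adhesion gene Sele (11.6 CPM against 0.741 CPM, log2 ratio 3.86) were highest, and Esm1 at -2.81 and Angpt2 at -2.50 lowest. All 36 interferon response genes measured were higher, with a median of 1.00 (0.95 to 1.10), led by Zbp1 at 3.03 and Irf7 at 2.34, with Bst2 at 0.28 and Ifih1 at 0.35 lowest. Inflammatory cytokine and chemokine genes lay at 0.82 (0.69 to 1.07), between Il1rn and Csf1, both at 2.24, and Ccl4 at -0.52 and Ccl8 at -3.52. Barrier and quiescence genes lay at 0.19 (0.16 to 0.30), with lipoprotein lipase, Lpl, at 3.01 and Angptl4 at 1.81 highest and Kdr, the main receptor for vascular endothelial growth factor, at -1.36 and Tjp1 at -0.54 lowest. Named by size, Spock2 at 5.09, the transcription factor Zbtb16 at 4.77 and Fam107a at 4.62 were highest, and the clock gene Dbp at -3.47, Tnfrsf21 at -3.26 and the apelin receptor Aplnr at -3.06 lowest. Neutrophil markers in the class were 1073 CPM in CLP, of which Lcn2 made up 537 CPM, and 121 CPM in sham. Macrophage markers were 426 and 1041 CPM, and smooth muscle markers 307 and 131 CPM. All genes of the class had a median of -0.13.

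Fibroblast-like cells of CLP were higher in acute phase genes and lower in extracellular matrix genes. The acute phase and metal response list had a median of 1.48 (1.41 to 1.51), with 21 of 25 members higher and a percentile of 100. Lipocalin 2, Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), was 2858 CPM in CLP and 2.24 CPM in sham, a log2 ratio of 10.29. It was not particular to the class, as macrophage-like cells of CLP held 3170 CPM, endocardial-like 3717 CPM, lymphatic endothelial-like 12449 CPM and neutrophil-like 14055 CPM. Saa3 was 8.31 log2 units higher, but its 4303 CPM in fibroblast-like cells lay below the 5711 CPM of cardiomyocyte-like cells. Socs3 at -0.57 and Cebpd at -0.43 were the lowest members. Extracellular matrix genes had a median of -1.11 (-1.14 to -1.01), with 24 of 28 lower; Col15a1 at -3.13 and Col14a1 at -2.51 were lowest, and the crosslinking enzyme Lox at 2.09 and Col4a1 at 0.78 highest. Interferon response genes lay at 0.84 (0.80 to 0.97), with 34 of 36 higher, from Zbp1 at 2.86 and Ifi44 at 2.73 to Isg20 at -0.02, which turned positive under TMM scaling, and Irgm1 at -0.96. Inflammatory cytokine and chemokine genes lay at 0.13 (-0.04 to 0.33), with Csf3 at 5.07 and Il1rn at 2.27 highest and Tnf at -0.74 and Ccl2 at -0.69 lowest.

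Named by size in fibroblast-like cells, Saa2 had 950 counts in CLP and 1 in sham, a log2 ratio of 8.88 (6.99 to 14.77), and Serpina3m 1009 counts against 2, a ratio of 8.23 (6.70 to 11.60). Chil1 followed at 7.89, and Col2a1 at -6.19, Spon2 at -3.53 and Col6a6 at -3.37 were lowest. Neutrophil markers in the class were 3291 CPM in CLP, of which Lcn2 made up 2858 CPM, and 293 CPM in sham. Macrophage markers were 2624 CPM and 5398 CPM, endothelial markers 542 CPM and 173 CPM, and endocardial markers 48.1 CPM and 236 CPM. With 5 CPM added to both values the acute phase median was 0.80. All genes of the class together had a median of -0.09.

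Neutrophil-like cells of CLP held more transcripts of the secondary granule genes Camp and Ltf than those of sham, where both were also lower than in control. Cathelicidin, Camp (ENSMUSG00000038357, chromosome 9, 109847379 to 109849617), had 4267 counts in CLP and 2 in sham, a log2 ratio of 9.44 (7.91 to 12.81). Lactoferrin, Ltf, with 1172 counts against 0, was at least 159-fold higher, and the acid glycoprotein Orm1, with 203 against 0, at least 27.6-fold higher. In control the class held 1664 CPM of Camp and 295 CPM of Ltf, against 2.76 CPM and 0 in sham, and Lcn2 stood at 1466 CPM in sham. Sirpb1c at -3.96, Jaml at -3.90 and Fgl2 at -3.89 were lowest. Monocyte markers in the class were 4626 CPM in CLP and 1307 CPM in sham, macrophage markers 527 and 2858 CPM, and B cell markers 46.7 and 386 CPM. Of the 18 measured members of the granule and maturation list, 8 were higher and 10 lower, with Ccrl2 at -1.78 and Cxcr4 at -1.72 lowest. The median was -0.24 (-0.49 to -0.07), the mean 1.59 and the median under TMM scaling 0.06, so the list had no single direction. The median of all its genes was -0.30, and its depth was a median of 6292 UMIs in CLP and 2681 in sham.

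CLP plus stimulation over CLP is the comparison the series title is about. Macrophage-like cells were 31.7% (30.7 to 32.7) of cells with stimulation and 22.3% (21.4 to 23.2) without, a log2 ratio of 0.51 (0.42 to 0.60). Neutrophil-like cells were 5.20% (4.72 to 5.71) against 2.96% (2.59 to 3.36), a ratio of 0.81 (0.58 to 1.05), and monocyte-like cells 9.17% (8.55 to 9.83) against 2.97% (2.60 to 3.37). Neutrophil markers in monocyte-like cells were 14400 CPM with stimulation and 26877.5 CPM without, and macrophage markers 1487 and 5527 CPM. T or NK cell-like cells were 6.12% (5.61 to 6.67) against 1.15% (0.924 to 1.41). Endothelial-like cells were 8.34% (7.74 to 8.97) against 28.7% (27.7 to 29.7) and fibroblast-like cells 15.3% (14.5 to 16.1) against 26.1% (25.2 to 27.1). Kept cells had median depths of 5010.5 and 5491 UMIs, and unnamed cells were 18.7% against 4.10%. Among immune cells alone the macrophage-like direction turned, at 58.4% against 73.9%, a log2 ratio of -0.34, and neutrophil-like cells were level, at 9.58% against 9.81%, a ratio of -0.03. That total leaves out all unnamed cells, which with stimulation were mostly cluster 10. With at least 1000 UMIs and 500 genes per cell the neutrophil-like ratio was 1.99, at Leiden resolution 2 it was 1.498, and with cluster 10 counted as neutrophil-like 2.36.

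In macrophage-like cells the M1 and the M2 list were both higher with stimulation. The M2 median was 0.62 (0.25 to 0.76), with 15 of 21 members higher and a percentile of 99.99. Matched random lists lay mostly between -0.27 and 0.34, and most alternatives, given below, put the M2 median inside that range. The M1 median was 0.82 (0.74 to 0.85), with 12 of 20 members higher and a percentile of 100. The median of all genes in the class was 0.00. Set against sham, CLP plus stimulation had an M2 median of -1.13 (-1.22 to -0.82) but a mean of 0.28. Of 21 M2 members, 13 were lower, 11 of them at least 2-fold, and 8 were higher, 6 of them at least 2-fold. The M1 median was 1.10 (1.06 to 1.18). Of 20 M1 members, 12 were higher, 10 of them at least 2-fold, and 8 were lower, 4 of them at least 2-fold.

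Among M2 genes, Mrc1 was 918 CPM (904 to 932) with stimulation and 239.7 CPM (231 to 248) without, a log2 ratio of 1.94, against 806 CPM in sham. Cd163 (ENSMUSG00000008845, chromosome 6, 124304656 to 124330527) was 411 CPM (402 to 420) against 176 CPM (168 to 183), a ratio of 1.23. The chemokines Ccl17 at 4.18 and Ccl24 at 2.27, with Retnla at 2.10, Mgl2 at 1.85 and Il4ra at 1.06, were higher, and Ccl22, with 20 counts against 1, at 3.15 (1.06 to 9.08). Ccl17 and Retnla were also among the top genes of unnamed cluster 25, which held 1.81% of cells with stimulation and 0.594% without. Retnla at 74.4 CPM, Ccl24 at 45.5 CPM and Mgl2 at 35.6 CPM stayed under their sham levels of 220.2, 245 and 829 CPM. Clec10a at 0.72, Arg1 at 0.67, Chil3 at 0.62, Klf4 at 0.24 and Folr2 at 0.11 were higher by less. Chil3, the member at the median, gained 2.14 CPM here and 7.85 CPM in endothelial-like cells, and Ccl17, Il4ra, Tgm2 and Irf4 were likewise not particular to the class. Myc at -1.33, Pparg at -0.73, Stab1 at -0.51 and Tgfb1 at -0.39 were lower. Tgm2 at 0.19, Irf4 at 0.16, Il10 at -0.02 and Egr2 at -0.03 lay within counting error, and Il10 turned positive under TMM scaling. The M2 median lay between 0.21 and 0.29 in 8 of 13 alternatives, lowest without the members that are also cell type markers. Its middle members, Chil3 and Klf4, were far apart. These 8 values lie within the -0.27 to 0.34 of matched random lists in the main setting. Against that range they do not set the M2 list apart from matched random genes. No percentile is given for the alternatives.

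Among M1 genes, the chemokine Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518) was 159 CPM (153 to 164) with stimulation and 16.9 CPM (14.7 to 19.3) without, a log2 ratio of 3.23. Il1b was 814 CPM (801 to 827) against 311 CPM (301 to 321), a ratio of 1.39. Interleukin 6, Il6, at 2.48, Nos2 at 2.23, the costimulatory genes Cd80 at 2.09 and Cd40 at 1.61, Il1a at 1.71 and Cxcl9 at 1.52 were higher. Il6 gained 30.4 CPM here, less than in endothelial-like (77.7 CPM) or fibroblast-like cells (123.5 CPM). Ccl5 gained 141.7 CPM here and 57.0 CPM in endothelial-like cells, and was also higher in sham than in control. It was the top gene of T or NK cell-like cluster 18, and T or NK cell-like cells were 6.12% of cells with stimulation against 1.15%. Cd38 and Irf1, both at 0.90, Socs3 at 0.73 and Ptgs2 at 0.44 were higher by less. Marco at -1.75, Cxcl10 at -0.995, Tnf at -0.70, Irf5 at -0.32 and Cd86 at -0.27 were lower, and Il23a at -0.16 and Fpr2 at -0.07 lay within counting error. With cells thinned to 770 UMIs the M1 median was 0.39, while without thinning the M1 median of sham over control was 0.46. Neutrophil markers in the class were 7894 CPM with stimulation, of which Lcn2 made up 6757 CPM, and 3807 CPM without, and monocyte markers 597 CPM and 1073 CPM.

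MHC class II genes were the list with the highest median. All 7 measured members were higher, with a median of 2.87 (2.83 to 2.90). H2-Aa (ENSMUSG00000036594, chromosome 17, 34282744 to 34287823) was 791 CPM with stimulation, 72.6 CPM in CLP and 3244 CPM in sham, a log2 ratio of 3.44 over CLP. H2-Ab1 stood at 3.41, and H2-DMa at 0.60 and H2-DMb1 at 0.49 were the lowest members. Named by size, H2-Aa, the sphingosine kinase Sphk1 at 3.43 and H2-Ab1 were highest, and the monocyte chemokine Ccl12 at -3.90, Lst1 at -3.47 and Aif1, a marker gene of macrophages, at -3.46 lowest. Saa3 stood at 56064 CPM, near its 57551 CPM in CLP. The resident macrophage list lay at -0.12 (-0.25 to -0.01), with Ccl24 and Mrc1 highest and Cbr2 at -2.13 and Igf1 at -1.72 lowest. The monocyte-derived list lay at 0.41 (0.26 to 0.55), with F10 at 2.84 and Thbs1 at 1.94 highest and Ms4a4c at -3.21 and Spp1 at -1.44 lowest. Phagocytosis and efferocytosis genes lay at -0.38 (-0.46 to -0.37), with Lrp1 at 1.10 and Mertk at 0.92 highest and Marco and Cd36 at -1.28 lowest. Inflammatory cytokine and chemokine genes lay at 0.56 (0.54 to 0.58), with Cxcl5 at 3.37 and Il6 highest and Ccl12 and Ccl6 at -1.997 lowest. Interferon response genes lay at -0.55 (-0.63 to -0.40), with 26 of 35 lower, from Gbp2 at 0.93 and Stat2 at 0.46 to Oas1a at -1.84 and Ifi27l2a at -1.98.

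**Figure D3:**
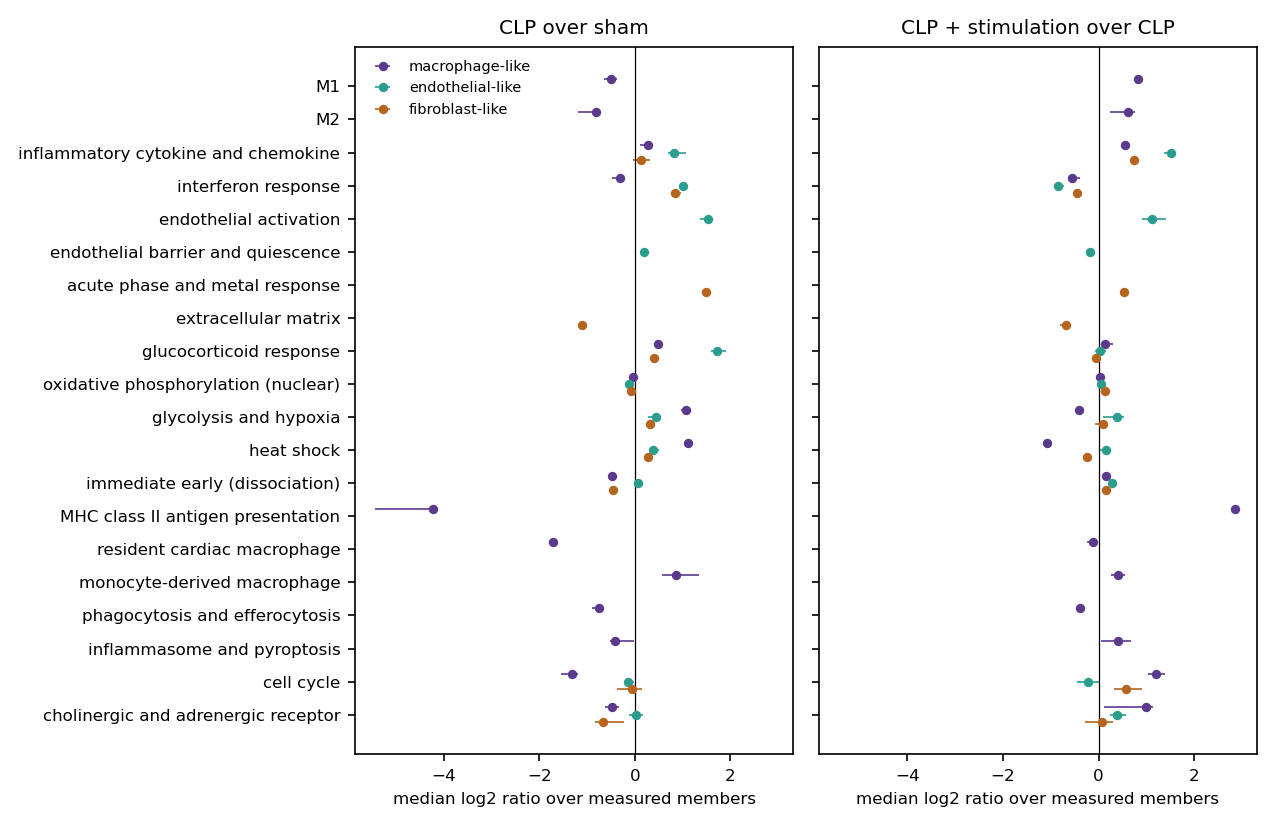
Median log2 ratio (horizontal axis) of each gene list over its measured members in macrophage-like, endothelial-like and fibroblast-like cells, for CLP over sham and CLP plus stimulation over CLP, with lines for 95% counting intervals. MHC class II genes moved furthest, to -4.22 and then 2.87; oxidative phosphorylation medians for CLP over sham, the fibroblast-like glucocorticoid median for CLP plus stimulation over CLP and the fibroblast-like cell cycle median for CLP over sham change sign under TMM scaling.

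Endothelial-like cells with stimulation were higher in activation and inflammatory genes and lower in interferon response genes. The activation list had a median of 1.12 (0.91 to 1.41), with 17 of 21 members higher and a percentile of 100. Csf3 (ENSMUSG00000038067, chromosome 11, 98701263 to 98703629) was 89.5 CPM with stimulation and 1.96 CPM without, below the 333 CPM of neutrophil-like cells, and Il6 at 2.85 came next, while Icam2 at -1.84 and von Willebrand factor, Vwf, at -1.32 were lowest. Inflammatory cytokine and chemokine genes lay at 1.51 (1.36 to 1.61), with Csf3 and Il1rn at 3.00 highest and Ccl12 at -2.39 and Ccl6 at -1.20 lowest. Interferon response genes lay at -0.84 (-0.90 to -0.72), with 32 of 36 lower, from Gbp5 at 0.54 and Ifitm3 at 0.39 to Ifi44 at -2.34 and Oas2 at -2.38. Barrier and quiescence genes lay at -0.17 (-0.24 to -0.11), with the tight junction gene Cldn5 at 1.86 and Procr at 1.12 highest and thrombomodulin, Thbd, at -1.94 and Angptl4 at -1.92 lowest. Named by size, Sh2d5 had 307 counts against 3, a ratio of 8.37 (7.03 to 10.88), followed by the activin subunit Inhbb at 6.11 and AA467197 at 5.46. The glycerol channel Aqp7 had 3 counts against 1046, a ratio of -6.31 (-8.81 to -4.98), Vwa3a 3 against 633, a ratio of -5.59 (-8.09 to -4.25), and Slc26a10 stood at -4.47. The class held 669 cells against 2223, its neutrophil markers were 7021 CPM, mostly Lcn2 at 6308 CPM, against 1073 CPM, and its pericyte markers 859 CPM against 381 CPM. All its genes together had a median of -0.12.

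Fibroblast-like cells with stimulation were again higher in acute phase genes and lower in matrix genes. The acute phase and metal response list had a median of 0.53 (0.52 to 0.57), with 20 of 25 members higher and a percentile of 100. Orm1 at 4.95 and metallothionein 1, Mt1, at 1.70 were highest, and the complement genes Cfb at -1.36 and C3 at -1.31 lowest. Extracellular matrix genes lay at -0.67 (-0.81 to -0.64), with 23 of 28 lower; Col3a1 at -1.80 and Col6a2 at -1.71 were lowest, and tenascin C, Tnc, at 2.02 and Lox at 0.66 highest. Interferon response genes lay at -0.44 (-0.51 to -0.35), with Ifi47 at 1.00 and Ifi207 at 0.63 highest and Oas1a at -1.96 and Ifi27l2a at -3.09 lowest. Inflammatory cytokine and chemokine genes lay at 0.75 (0.67 to 0.80), with Il1a at 3.82 and Csf3 at 3.21 highest and Ccl12 at -2.72 and Il18 at -1.45 lowest. Named by size, the prostaglandin-degrading enzyme Hpgd at 4.66, Ly6k at 3.98 and Mcoln2 at 3.34 were highest, and Cd248 at -3.09 and Ifi27l2a among the lowest. Neutrophil markers in the class were 5182 CPM, of which Lcn2 made up 4718 CPM, against 3291 CPM. Endothelial markers were 1332 CPM against 542 CPM, and all genes of the class had a median of -0.21.

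Neutrophil-like cells with stimulation had a granule and maturation median of 0.37 (0.24 to 0.62), with 12 of 18 members higher. The median of all genes in the class was 0.29, and TMM scaling lowers each ratio by 0.29. The immune checkpoint ligand Cd274 at 2.21 and the chemokine Ccl3 at 1.88 were the highest members, and the receptor Cxcr2 at -1.62 and the collagenase Mmp8 at -1.40 the lowest. Named by size, Csf3 at 3.27, the stress cytokine Gdf15 at 3.03 and Fmnl2 at 2.90 were highest; each was higher still in another class of the library, at up to 1507, 294 and 424 CPM against 333, 167 and 56.3 CPM here. The lowest were Cdk5r1 at -3.96, Acvrl1 at -3.24 and Ndrg1 at -2.84. The class held 417 cells with stimulation and 229 without, at median depths of 5609 and 6292 UMIs. Monocyte markers in it were 5792 CPM with stimulation and 4626 CPM without, and macrophage markers 523 and 527 CPM. NK cell markers were 46.6 and 153 CPM, and endothelial markers 171 and 370 CPM.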

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

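The test of damaged cells was chosen only after its result could be seen; the other tests of unnamed cells were written down beforehand. Several gene lists had medians of opposite sign in different cell classes of the same comparison, and these differences were not tested. In CLP over sham, the interferon response median was 1.00 in endothelial-like and 0.84 in fibroblast-like cells but -0.32 in macrophage-like cells, where TMM scaling left -0.085. Immediate early genes, which cell dissociation can induce, lay at 0.067 in endothelial-like, -0.49 in macrophage-like (-0.25 under TMM scaling) and -0.45 in fibroblast-like cells. In CLP plus stimulation over CLP, glycolysis and hypoxia genes lay at 0.39 in endothelial-like and -0.40 in macrophage-like cells. Heat shock genes lay at 0.15 in endothelial-like, -1.08 in macrophage-like and -0.24 in fibroblast-like cells, the last of these -0.039 under TMM scaling. Such values near 0 after scaling follow the shift of all genes in the class.

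Unnamed cluster 10 made up 16.9% of the CLP plus stimulation library, or 1354 cells, which were part of the total for shares but of no expression comparison; its cells there had a median of 986 UMIs, against 6480 in the other cells. Droplets with free RNA and no cell would share 1 mixture, but neutrophil, fibroblast and T or NK marker counts varied between barcodes by 26.4, 8.79 and 4.17 times the Poisson variance. This argues against such droplets as the whole set only, since some cells among many empty droplets would raise these values too. Neutrophils with few UMIs are also argued against as the whole set, since neutrophil markers led in 43.4% of the barcodes, with macrophage markers leading in 36.9%, fibroblast markers in 15.2% and endothelial markers in 4.21%. Ties with neutrophil markers were counted as neutrophil. These markers include Lcn2, at 6757 CPM in macrophage-like, 6308 CPM in endothelial-like and 4718 CPM in fibroblast-like cells of this library. A barcode led by neutrophil markers therefore need not be a neutrophil. A candidate explanation that stays open is damaged cells of several types, as the median mitochondrial share was 1.79 times that of the other cells (3.79% against 2.11%). The library had the lowest median share over all its barcodes, at 2.35%. The 3.79% of cluster 10 was near the medians over all barcodes of CLP (3.80%) and sham (3.71%), so it is a weak sign of damage. Stimulation itself was not tested, because the group has 1 library.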

How the results depend on the processing

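Of 128 recomputed values, 85 stayed within counting error of the value reported, 41 moved beyond it with the same direction and 2 reversed. No paired analysis was possible because each group has 1 library. Alternatives with unnamed clusters, cell type marker members or cluster 29 were chosen after seeing the data. For all shifts the cause was not tested. Values are log2 ratios, with CLP over sham given before CLP plus stimulation over CLP.

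With immune cells as the total, the macrophage-like share lay at -0.083 and reversed to -0.34. The neutrophil-like share lay at 0.84 and, with its sign reversed but near 0, at -0.034. The smaller total leaves out endothelial-like, fibroblast-like and other non-immune cells. It also leaves out all unnamed cells, which were 18.7% of CLP plus stimulation and 4.10% of CLP. With stimulation 90.1% of them were in cluster 10, where neutrophil markers led in 43.4% and macrophage markers in 36.9% of barcodes. The neutrophil markers include Lcn2, which other classes of that library also carried, so barcodes they led need not be neutrophils. With a mitochondrial limit of 10% the macrophage-like share lay at -0.86 and 0.66, and the M1 list of the later comparison at 0.90. With at least 1000 UMIs and 500 genes the macrophage-like share lay at -0.61 and 0.65, the neutrophil-like share at 0.49 and 1.99, and the M1 list of CLP over sham at -0.32. With monocyte-like cells added the macrophage-like share lay at -0.60 and 0.69, and with unnamed cells left out at 0.75 in the later comparison. With cluster 10 counted as neutrophil-like, that share lay at 0.71 and 2.36. At Leiden resolution 2 the neutrophil-like share with stimulation lay at 1.498, the M1 list of CLP over sham at -0.34, and the M2 and acute phase lists with stimulation at 0.22 and 0.43.

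With TMM scaling, CLP over sham lay at -0.27 for M1, -0.58 for M2, 1.67 for endothelial activation and 1.58 for acute phase genes, and acute phase genes with stimulation at 0.73; the scaling adds the same shift to every gene of a class. With 5 CPM added, which draws low genes toward 0, M1 with stimulation lay at 0.57, endothelial activation at 1.15 and 0.85, and acute phase genes of CLP over sham at 0.80. With cells thinned, M1 lay at -0.12 and 0.39, endothelial activation of CLP over sham at 1.27, and acute phase genes at 1.30 and 0.65. With members of at least 1 count, M1 with stimulation lay at 0.90. With doublets kept, M2 with stimulation lay at 0.22 and acute phase genes at 1.58 and 0.48. Without cluster 29, M1 of CLP over sham lay at -0.35 and M2 with stimulation at 0.22; with cluster 25 counted as macrophage-like, M1 with stimulation lay at 0.87. Without members that are also cell type markers, M2 with stimulation lay at 0.21. A mitochondrial limit of 10%, at least 1000 UMIs, 5 CPM added and thinning gave 0.29, 0.26, 0.25 and 0.25, near the lower end of its interval (0.25 to 0.76). These M2 values, and those of 0.21 and 0.22, lie within the -0.27 to 0.34 of matched random lists in the main setting.

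Depth limits single genes: several named genes in macrophage-like, endothelial-like, fibroblast-like and neutrophil-like cells rest on 3 counts or fewer in the lower library.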

Other observations

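The tests of monocytes, of B cells and of dendritic cells reported here were chosen only after the result was seen; those of free RNA were written down beforehand. Macrophage-like cells of CLP were higher than those of sham in heat shock genes, with a median log2 ratio of 1.11 over 15 of 15 members, among them the chaperones Hsph1 at 2.73 and Hspa1b at 2.34. With stimulation all 15 were lower than in CLP, at -1.08, with Hspa1b at -2.39. The median mitochondrial share, a sign of cell quality, was 5.21% in the main macrophage-like cluster of CLP (9) and 2.25% in that of CLP plus stimulation (4), the clusters that also carry the M1, M2 and MHC class II differences. These medians are over all cells of a cluster, from any library. The share lay at 3.15% in cluster 0 (1792 control and 1519 sham cells) and 10.1% in the smaller cluster 11 (870 and 357). Both hold more control than sham cells, so neither gives a value for sham alone. Glycolysis and hypoxia genes in the class lay at 1.06 (0.97 to 1.14) in CLP over sham, with the lactate exporter Slc16a3 at 2.62 and the glucose transporter Slc2a1 at 2.08, and at -0.40 (-0.46 to -0.35) in CLP plus stimulation over CLP, where the hypoxia factor Hif1a stood apart at 1.43. Cell cycle genes lay at -1.31 (-1.55 to -1.19) and then at 1.21 (1.04 to 1.38), with Mki67 at 2.58 in the latter. Proliferating cluster 29, led by such genes, held 72 of the 3064 macrophage-like cells of sham, 11 of the 1726 of CLP and 84 of the 2541 with stimulation. Inflammasome and pyroptosis genes lay at -0.41 (-0.53 to -0.01) and 0.40 (0.05 to 0.67), with Nlrp3 at 1.63 with stimulation. Glucocorticoid response genes lay at 0.48 and 0.14 in macrophage-like, 1.73 (1.60 to 1.90) and 0.04 in endothelial-like, and 0.40 and -0.06 in fibroblast-like cells, the last of these turning to 0.14 under TMM scaling. In endothelial-like cells the metallothionein Mt2 stood at 4.75 with stimulation.

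Receptors through which nerves might act were scarce. Of the cholinergic and adrenergic list, 4 members could be measured in macrophage-like cells of CLP over sham, with a median of -0.48, and 5 with stimulation, with a median of 0.99 (0.12 to 1.14) that rested on the signalling genes Stat3 at 1.10 and Jak2 at 0.99. The nicotinic receptor gene Chrna7 did not reach 20 counts. The list lay at 0.03 and 0.39 in endothelial-like and at -0.66 and 0.07 in fibroblast-like cells. Oxidative phosphorylation genes lay at -0.05 and 0.02 in macrophage-like, -0.11 and 0.05 in endothelial-like and -0.08 and 0.14 in fibroblast-like cells, the CLP over sham values turning positive under TMM scaling. Immediate early genes with stimulation lay at 0.15, 0.28 and 0.15 in the same classes. Heat shock genes of CLP over sham lay at 0.39 in endothelial-like and 0.28 in fibroblast-like cells, glycolysis and hypoxia genes at 0.44 and 0.31, and with stimulation at 0.10 in fibroblast-like cells. Cell cycle genes lay at -0.14 and -0.21 in endothelial-like and at -0.05, which turned to 0.04 under TMM scaling, and 0.58 in fibroblast-like cells.

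M1 and M2 genes were both higher with stimulation in macrophage-like cells. In most alternatives, however, the M2 median lay within the main setting's range of matched random lists. Whether monocytes were counted in the class could not be decided. The 10 monocyte markers outside both lists had a median log2 ratio of -0.34 (-0.56 to -0.26). The monocyte-derived macrophage list went the other way, at 0.41 (0.26 to 0.55) with 13 of 18 members higher. Monocyte-like cells were also a larger share of cells, at 9.17% against 2.97%. Free RNA of other cells cannot be told apart from a gain within the class, since 77.8% of the higher members (21 of 27) gained over 2 times as many CPM there as in endothelial-like and fibroblast-like cells, short of the 80% set beforehand; the 6 others were Il6, Chil3, Ccl17, Irf4, Il4ra and Tgm2. Retnla, Ccl17 and Il1b were among the top genes of unnamed cluster 25, which held 1.81% of cells with stimulation and 0.594% without. Such cells counted in the class were not tested for the M1 and M2 genes and stay open. A library difference other than stimulation stays open too, because there is 1 library per group, and so does stimulation itself.

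MHC class II genes were low in CLP and partly higher with stimulation in macrophage-like cells. Free RNA of other cells, which would reach all classes alike, is argued against as the whole gain, but only by comparison with 2 classes. Of the measured members, 85.7% (6 of 7, without H2-DMb1) gained over 2 times as many CPM here as in endothelial-like and fibroblast-like cells. Other classes were not part of that test. H2-Aa was also higher in endocardial-like (10.2 to 387 CPM), T or NK cell-like (254 to 515) and smooth muscle-like cells (0.978 to 139). It was higher too in endothelial-like (5.87 to 74.0), pericyte-like (3.76 to 48.8) and unnamed cells (802 to 3221), the last mostly of different clusters in the 2 libraries. Fibroblast-like (2.68 to 12.6) and cardiomyocyte-like cells (44.6 to 44.7) gained few CPM. Neutrophil-like cells were level (124 to 125), and B cell-like (1196 to 860) and monocyte-like cells (167 to 137) were lower. B cells counted in the class are argued against as well: the gain in H2-Aa would need a share of 83.5%, and B cell markers gained -0.165% of what that share would bring. Dendritic cells counted in the class stay open as part of the gain. The summed dendritic markers gained 14.3% of what a share of 11.3% cluster 25 cells would bring (7.34 CPM of 51.2 CPM). This lay between the bounds of 10% and 50% set for a verdict. Cluster 25 scored alike for macrophage and monocyte markers, so it is not a clear dendritic reference and the percentage cannot decide. A library difference other than stimulation, with 1 library per group, and stimulation itself stay open.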
